A study of Mus musculus with 18 samples.

How the data were processed

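RNA was extracted with TRIzol from colon scrapings of male C57BL/6J mice and measured on 18 Affymetrix Mouse Gene 1.1 ST arrays of 1 colour. The array type was taken from the probe table. The labels place the arrays in 4 groups, control (4), control plus antibiotics (4), heme (4) and heme plus antibiotics (6). They describe the replicates as separate samples, so p-values measure the spread between samples, and whether each is a separate mouse is not stated. The time of day at which tissue was taken was not in the labels.

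The deposited values are log2 expression values made by the authors with RMA (background correction, quantile normalization and summary per transcript cluster), per the submitters' processing notes. The version of that software is not given in the sources used here. Values ran from 1.78 to 13.89, with medians of the arrays between 5.65 and 5.84, and no further scaling was applied. The number of arrays limits the precision.

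The table held 35556 transcript clusters. Of these, 21218 had 1 gene symbol in the probe table, 1881 had several and 12457 were not listed. Gene IDs of 21185 of the 21218 matched the reference gene table, from which current symbols were taken. The 21218 clusters covered 18820 genes. Where a gene had several clusters (1386 genes) the one with the highest mean over all arrays was used. Among genes named by parts 1 and 3 of the rule below, 2 had several clusters, and these were compared. Clusters of genes named only as list members were not compared. The 3 clusters of Hspb1 ranged from -2.06 to -0.02 for heme without antibiotics and from -0.0083 to 2.45 for the difference of the heme effects. The 2 of Fer1l4 had the same direction as each other in every comparison. They ranged from -2.04 to -1.62 for that difference and from 0.52 to 1.05 for antibiotics on the control diet. Genes above 20 on the linear scale on at least 4 arrays were kept, which left 14639. Clusters with no single gene symbol were counted in a separate fit and not named.

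Groups were compared with limma 3.58.1 under R 4.3.3. A mean was fitted for each of the 4 groups over all 18 arrays, followed by empirical Bayes moderation (prior degrees of freedom 4.22, total 18.2) and 2-sided tests. P-values were adjusted by Benjamini-Hochberg within each of 5 comparisons, and a gene was called below 0.05. The comparisons were heme against control without antibiotics, the same with antibiotics, the difference of both heme effects, and antibiotics against none on each diet. Errors of group means are SD and errors of log2 changes are SE. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

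Lists of genes for pathways and cell types were fixed before the data were examined, as were the tests, the other settings to be tried and the rule for naming genes. Of 40 lists with 778 members, 672 members were measured above the minimum, 32 lay below it and 74 found no match. Lists with at least 5 measured members were tested, which left out red blood cells and kept 39. Camera, with a preset inter-gene correlation of 0.01, set each list against all other genes, with adjustment over the 39 lists. It called 19 lists for heme without antibiotics, 21 with antibiotics, 20 for the difference, and 19 for antibiotics on each diet. With an estimated correlation 0, 2, 1, 0 and 0 lists were called, and 8, 14, 7, 9 and 6 had an unadjusted p below 0.05. The lists called were NRF2 targets and PPAR targets for heme with antibiotics and enteroendocrine genes for the difference. Fry, which asks whether a list's genes move one way on balance, called 27, 15, 19, 20 and 9. A count "adjusted over the list alone" adjusts over the members of that list in place of all tested genes. Hmox1 alone stood on more than 1 list, and no smooth muscle or neuron gene stood on another.

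Genes were named by 3 parts of a rule. Part 1 takes, per comparison, the 10 largest rises and the 10 largest falls among called genes whose values do not overlap between groups, a condition that the difference of effects lacks. Part 2 takes up to 4 members of each described list, those called with the largest change. Part 3 takes Hmox1, Mki67, Birc5, Muc2, Reg3g, Wif1 and Car1 as references, while Areg was not analysed here. Clone names, receptor segments and small RNAs were left out of part 1.

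The labels number the replicates within each group. Deviations from the group means of same-numbered heme and control arrays without antibiotics correlated at 0.25, 0.14, 0.11 and 0.27 for numbers 1, 2, 3 and 4. As all 4 lie above 0.1, the replicate number as a block was tried for this comparison, and its value stands beside a result where it changes the call. Array 2 and array 4 did not match best with their own numbers, and the labels give no litter, batch or day behind the numbers.

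The fit was tested on simulated data with the spread of these arrays. Over 5 runs with 200 changed genes it recovered 67% of changes of 0.5 and 94.8% of changes of 1 on the log2 scale for heme without antibiotics, 76.8% and 98% with antibiotics, and 39.8% and 88.4% for the difference. False calls were 3.35%, 4.48% and 5.46%. A list of mitosis genes shifted by 0.5 was called in 20 of 20 runs, with 0 other lists called by camera per run. The simulated genes varied independently of one another. These runs therefore do not show how limma or camera behave with genes that move together.

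Other settings fixed at that point were other filters on dim genes, the mean of a gene's clusters, centring of arrays, quantile normalization, a mean-variance trend, array weights, only the groups compared, the replicate block and each array left out in turn, and for lists also camera on ranks, fry and an estimated correlation. Chosen after seeing the data were the smooth muscle score as a covariate, the control group without its 3 arrays of highest score, lower or upper replicate numbers as a block, and the arrays of lower or of upper numbers alone. Lower numbers are 1 and 2, or 1 to 3 in heme plus antibiotics. A list's score is the mean log2 expression of its measured members on an array.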

Results

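Gene expression was measured in scrapings of mouse colon with 1-colour arrays, 18 in all. Male C57BL/6J mice, an inbred laboratory strain, aged 11 weeks, ate a fat-rich Western-type diet for 14 days. Heme, the iron-containing pigment of red meat, was added at 0.5 µmol per g diet in 2 of the 4 groups. A mixture of ampicillin, neomycin and metronidazole, which kills many gut bacteria, was in the drinking water of 1 control group and 1 heme group. The control, control plus antibiotics and heme groups had 4 arrays each, and the heme plus antibiotics group had 6. The values were deposited log2 expression values, which ran from 1.78 to 13.89. Arrays of one group correlated across the tested genes with r between 0.984 and 0.996. The number of arrays limits the precision of every value below.

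A scraping can hold cells from under the epithelium as well as epithelium, and the level of muscle transcripts differed between groups. The mean log2 expression of 14 smooth muscle genes was 10.04 ± 0.71 (SD, n = 4) in control. It was 8.60 ± 0.57 (n = 4) in control plus antibiotics, 8.52 ± 0.35 (n = 4) in heme and 8.88 ± 0.73 (n = 6) in heme plus antibiotics. Control replicates 1, 2 and 3 lay at 10.32, 10.60 and 10.23, and control replicate 4 lay at 8.99. Every comparison that involves the control group without antibiotics therefore also compares scrapings with different levels of muscle transcripts. Settings below that leave out control replicates 1, 2 and 3 keep a lone control array. A call that ends or appears there can come from the lone control.

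**Figure D1:**
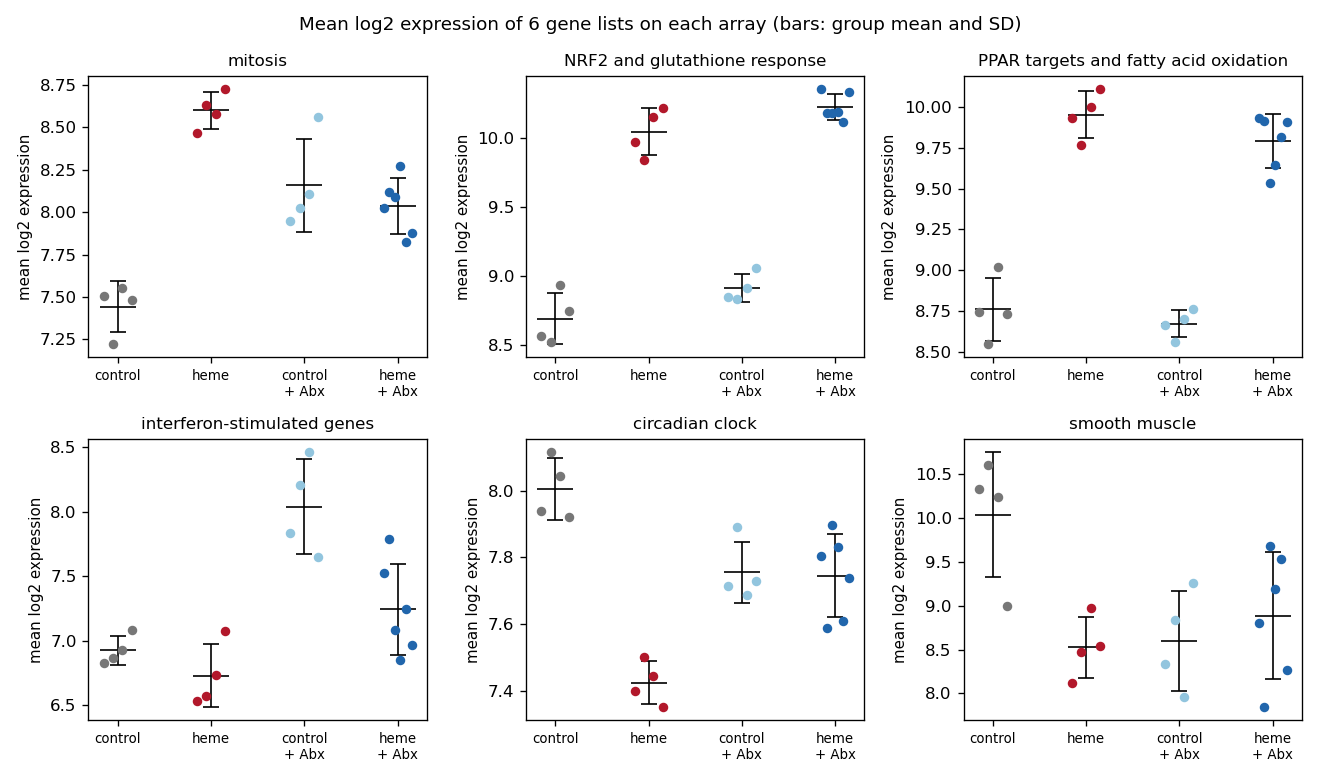
Mean log2 expression of 6 gene lists on each of the 18 arrays, 1 point per array, with the group mean and SD as bars; + Abx marks antibiotics in the drinking water. Mitosis scores averaged 7.44 in control and 8.60 in heme without antibiotics, but 8.16 and 8.03 with antibiotics, whereas NRF2 scores rose with heme from 8.69 to 10.04 and from 8.91 to 10.22.

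The first comparison asked what dietary heme changes in the colon when the gut bacteria are left in place. Heme raised Fabp1, which encodes the liver-type fatty acid carrier, from a log2 value of 4.60 ± 0.27 to 9.61 ± 0.61 (SD, n = 4 each), a 32.0-fold rise from a level near the filter's minimum of 20 on the linear scale. Hmox1, the enzyme that breaks heme down, rose 12.7-fold, from 5.95 ± 0.18 to 9.62 ± 0.30. All 25 measured mitosis genes rose, by a median of 1.17 on the log2 scale, together with genes of antioxidant defence and of fatty acid oxidation. Of 16 clock genes 11 fell and 3 rose, and of 23 enteroendocrine genes 13 fell and 1 rose. Tuft cell genes fell in 10 of 16 cases, smooth muscle genes in 13 of 14 and neuron and glia genes in 10 of 13. In all, 2171 genes were higher and 2282 lower among 14639 tested, and 444 of these differed at least 2-fold.

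Mitosis genes rose as a group on heme (25 of 25 over all genes tested and 25 adjusted over the list alone, camera adjusted p = 1.42e-24, and adjusted p = 0.113 with an estimated correlation). Examples were the kinases Aurka (1.39 ± 0.18 SE), Bub1 (1.39) and Cdk1 (1.30) and the cyclin Ccna2 (1.36). The proliferation marker Mki67 rose by 0.89 ± 0.13 (adjusted p = 4.87e-05) and Birc5 by 1.21 ± 0.14. Of 25 genes of DNA replication and S phase, 19 rose and none fell (23 rose adjusted over the list alone), by a median of 0.55 (adjusted p = 1.92e-09, and adjusted p = 0.337 with an estimated correlation). Rrm2 and Rrm1, subunits of ribonucleotide reductase, rose by 1.60 and 0.86, and the thymidine kinase Tk1 by 0.85. Over the same arrays the smooth muscle list fell by a median of 1.71. The mitosis median was 1.22 within the arrays of lower replicate numbers and 1.14 within those of upper numbers.

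The NRF2 and glutathione list, which holds targets of an oxidant-sensing transcription factor, had 22 of 25 members higher and none lower (24 adjusted over the list alone). Its median change was 0.98 (adjusted p = 3.32e-22, and adjusted p = 0.113 with an estimated correlation). The cystine transporter Slc7a11 rose by 3.62 ± 0.28, the carbonyl reductase Cbr3 by 3.29 ± 0.23 and the aldo-keto reductase Akr1b8 by 2.73 ± 0.18. PPAR targets and genes of fatty acid oxidation had 21 of 24 members higher and none lower (22 adjusted over the list alone), with a median of 0.69 (adjusted p = 3.05e-17, and adjusted p = 0.113 with an estimated correlation). Pdk4, a kinase that restrains pyruvate oxidation, rose by 2.85, the peroxisomal thiolase Acaa1b by 2.60 and the transcription factor Creb3l3 by 2.26. Oxidative phosphorylation genes rose less, by a median of 0.32 with 16 of 22 called (16 adjusted over the list alone, adjusted p = 1.84e-07, and adjusted p = 0.113 with an estimated correlation). Uqcrfs1 and Sdhb, subunits of respiratory complexes, rose by 0.65 and 0.48. Of 7 sulfide oxidation genes, 4 rose (5 adjusted over the list alone), led by Mpst at 1.00 (adjusted p = 0.0031, and adjusted p = 0.225 with an estimated correlation). Within lower and upper replicate numbers the NRF2 medians were 1.03 and 0.91, and the PPAR medians 0.78 and 0.66. The smooth muscle fall stood beside all of these lists.

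Circadian clock genes split by arm, with 11 of 16 lower and 3 higher on heme (11 and 3 adjusted over the list alone) and a median of -0.69. Per3 (-1.91), Ciart (-1.87) and Per2 (-1.47), which repress the core clock activators, fell (list adjusted p = 0.00082, and adjusted p = 0.113 with an estimated correlation). Tuft cell genes fell in 10 of 16 cases (12 adjusted over the list alone), with Gnat3 at -0.95 and Dclk1 at -0.87 (adjusted p = 8.21e-06, and adjusted p = 0.113 with an estimated correlation). Of 23 enteroendocrine genes, 13 fell and 1 rose, over all genes tested and adjusted over the list alone. The carboxypeptidase Cpe changed by -1.78 and the granule protein Chga by -1.35 (list adjusted p = 4.72e-05, and adjusted p = 0.113 with an estimated correlation). Among 17 genes that restrain growth through Wnt, hedgehog, BMP or interleukin signals, 4 fell (4 adjusted over the list alone), including Il15 (-1.22) and Bmp2 (-1.14). That list had an adjusted p of 0.0151, and adjusted p = 0.127 with an estimated correlation. The transmembrane mucin Muc1 fell by 1.48 within a junction and mucin list in which 5 of 17 members fell and 1 rose (6 and 1 adjusted over the list alone, adjusted p = 0.0129, and adjusted p = 0.378 with an estimated correlation). That list's adjusted p was 0.0502 without control replicate 4. The smooth muscle fall stood beside the lists of this paragraph as well. Cpe averaged 8.56 in control, 7.09 in control plus antibiotics, 6.78 in heme and 7.24 in heme plus antibiotics.

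Smooth muscle genes fell in 13 of 14 cases (14 adjusted over the list alone, median -1.71, adjusted p = 2.62e-06, and adjusted p = 0.379 with an estimated correlation). Neuron and glia genes fell in 10 of 13 cases (11 adjusted over the list alone, median -1.13, adjusted p = 4.7e-06, and adjusted p = 0.337 with an estimated correlation). Stmn2 fell by 2.09 and Snap25 by 1.89. Macrophage genes rose in 12 of 20 cases (14 adjusted over the list alone), led by Adgre1 at 0.90, and 10 of 19 cholesterol synthesis genes rose (12 adjusted over the list alone), led by Fdps at 0.90. Their adjusted p was 2.12e-05 and 4.72e-05, and for each adjusted p = 0.379 with an estimated correlation. Without the 3 control arrays of highest muscle score, the macrophage, muscle and neuron lists were no longer called. For muscle and neurons this is no separate evidence. The arrays were picked by their muscle score, and the neuron score moved with it.

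The heme and iron list (7 of 21 higher and 2 lower, 8 and 2 adjusted over the list alone, median 0.17) had an adjusted p of 0.0478, and adjusted p = 0.44 with an estimated correlation. With the replicate number as a block its adjusted p was 0.0524. It lay between 0.0516 and 0.0958 without control replicate 1, 2 or 4, control plus antibiotics replicate 1 or 3, heme replicate 3 or 4, or heme plus antibiotics replicate 4 or 6. The fibroblast and matrix list, with 9 of 18 lower and 2 higher over all genes tested and adjusted over the list alone, had a median of -0.38. Its adjusted p was 0.0478, then 0.08 with the replicate block, and adjusted p = 0.609 with an estimated correlation. It lay between 0.0513 and 0.264 without control replicate 2 or 4, any control plus antibiotics array, heme replicate 2 or 4, or heme plus antibiotics replicate 4, 5 or 6. The smooth muscle fall of 1.71 stood beside both lists.

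Other large rises included the calcium-activated channel regulator Clca4b (2.74 ± 0.39), Trim29 (2.71), the cornified envelope gene Sprr1a (2.62) and the antiprotease Slpi (2.61). Large falls included the sulfate transporter Slc13a1 (-2.47 ± 0.22), the manganese transporter Slc30a10 (-2.37) and the cytochrome P450 Cyp2f2 (-2.06). Mean log2 values also fell from control to heme for Epha7 (7.78 to 5.42), Nmu (6.25 to 3.97) and Pcp4 (9.07 to 6.97). Epha7, Nmu and Pcp4 had their highest group means in control, where muscle transcripts were also highest. Muc2, the main secreted colonic mucin, changed by -0.19 (adjusted p = 0.0436), from 13.38 to 13.19, near the highest array value of 13.89. This was a call that ended without the filter on dim genes, with quantile normalization, with array weights and with only both groups in the fit. The call ended too with the smooth muscle score as a covariate (-0.21, 0.188), without the 3 control arrays of highest score (-0.20, 0.38), and within lower (-0.13, 0.231) or upper numbers alone (-0.24, 0.114). It also ended without control replicate 1, 2 or 4, heme replicate 3 or 4, or heme plus antibiotics replicate 1, 2 or 6 (adjusted p 0.0503 to 0.118). The Wnt inhibitor Wif1 stood at -0.28 ± 0.15 and the carbonic anhydrase Car1 at 0.05 ± 0.06, and neither was called. Car1 too lay near the highest array value, at 13.16 in control and 13.20 in heme. Wif1 stood at -0.76 without the 3 control arrays of highest muscle score, a setting that keeps control replicate 4 as the only control.

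With the smooth muscle score as a covariate 1640 genes were called, and without the 3 control arrays of highest score 1013. Within lower replicate numbers alone 4089 genes were called, and within upper numbers alone 1395.

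The second comparison asked what heme changes in mice given antibiotics. Fabp1 rose by 3.91 ± 0.21, Cbr3 by 3.38 ± 0.21 and Hmox1 by 3.32 ± 0.16 (heme plus antibiotics n = 6, control plus antibiotics n = 4). No mitosis gene was called, and the heme plus antibiotics mean of Mki67 was 9.79 ± 0.18 against 9.91 ± 0.28 in its control. Interferon-stimulated genes, which encode antiviral proteins, fell in 18 of 22 cases. Heme raised 524 genes and lowered 283 here, and 104 of the 807 differed at least 2-fold.

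With antibiotics, the NRF2 and glutathione list had 22 of 25 members higher on heme and none lower (23 adjusted over the list alone), by a median of 0.84 (adjusted p = 3.71e-52, and adjusted p = 0.00434 with an estimated correlation). Akr1b8 rose by 2.89 and Me1, a source of NADPH, by 2.60. PPAR targets had 20 of 24 members higher and none lower (23 adjusted over the list alone), by a median of 0.67 (adjusted p = 1.1e-40, and adjusted p = 0.015 with an estimated correlation). Pdk4 rose by 2.81 and Acaa1b by 2.79. The smooth muscle list, with 0 of 14 members called by limma and 0 at an unadjusted p below 0.05, had a median of 0.28 in this comparison (fry adjusted p = 0.571). Medians within lower and upper replicate numbers were 0.91 and 0.85 for NRF2 targets, and 0.73 and 0.66 for PPAR targets.

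The sugar transporter family member Slc5a4b rose by 3.71 ± 0.19, the cytochrome P450 Cyp4a31 by 3.64 ± 0.24 and the export pumps Abcc2 and Abcc4 by 3.35 ± 0.22 and 2.92 ± 0.17. Slc5a4b and Cyp4a31 averaged 4.11 and 3.07 in control plus antibiotics, below the filter's minimum of 20 on the linear scale, so the sizes of their rises are not exact. In the xenobiotic metabolism list 7 of 16 members rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 2.46e-06, and adjusted p = 0.0902 with an estimated correlation). Abcc3 rose by 0.81 and the carboxylesterase Ces2a by 0.73. In the heme and iron list 6 of 21 members rose and 1 fell (9 and 1 adjusted over the list alone), among them the iron exporter Slc40a1 at 0.95 and the ferritin chain Ftl1 at 0.73. The heme and folate carrier Slc46a1 fell by 0.89 (list adjusted p = 2.37e-05, and adjusted p = 0.0902 with an estimated correlation). The smooth muscle median of 0.28 applies here too.

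The 18 of 22 interferon-stimulated genes that fell (21 adjusted over the list alone) had a list median of -0.70, with Ifit1 at -1.31 and Oas2 at -1.23 (adjusted p = 3.05e-21, and adjusted p = 0.0902 with an estimated correlation). Genes of antigen presentation by MHC class II fell in 6 of 9 cases (8 adjusted over the list alone), with H2-DMa at -0.95 and Cd74 at -0.87 (adjusted p = 3.76e-09, and adjusted p = 0.0902 with an estimated correlation). In the list of genes that respond to bacteria, 5 of 22 fell and none rose (9 fell adjusted over the list alone), including Duox2 and Duoxa2, which form an oxidase, at -1.0 and -0.96 (adjusted p = 1.2e-05, and adjusted p = 0.0902 with an estimated correlation). Ddx60 (-1.53 ± 0.27), Herc6 (-1.30) and the amino acid enzyme Tat (-1.28) were among the largest falls. Slc13a1 fell by 1.52. The immune cell lists had negative medians in the same comparison. T and NK cell genes fell in 5 of 19 cases (10 adjusted over the list alone, median -0.31, adjusted p = 3.76e-08, and adjusted p = 0.0902 with an estimated correlation). Of 20 macrophage genes limma called 0, with 0 adjusted over the list alone and 11 lower at an unadjusted p below 0.05 (median -0.24, adjusted p = 1.47e-05, and adjusted p = 0.318 with an estimated correlation, fry adjusted p = 0.101). Of 17 B and plasma cell genes limma called 0, with 3 lower adjusted over the list alone and 4 at an unadjusted p below 0.05 (median -0.20, adjusted p = 0.000119, and adjusted p = 0.318 with an estimated correlation, fry adjusted p = 0.101). A lower immune cell content and a lower expression per cell are not told apart here. Within lower and upper replicate numbers the interferon medians were -0.54 and -0.84.

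Mitosis genes had a median of -0.11 on heme with antibiotics, with 0 of 25 called by limma, 0 adjusted over the list alone and 2 lower at an unadjusted p below 0.05. Camera placed the list below other genes (adjusted p = 0.00267, and adjusted p = 0.626 with an estimated correlation), but its adjusted p was 0.205 with the replicate block and 0.717 without control plus antibiotics replicate 4. Fry gave an adjusted p of 0.406. Without control plus antibiotics replicate 2 or 3 the count of called genes was 524 or 528 in place of 807. Within lower replicate numbers alone 308 genes were called, and within upper numbers alone 371.

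The third comparison tested whether the heme effect itself differed with antibiotics, which is the question in the series title of what the microbiota contributes. All 25 mitosis genes had a smaller heme effect with antibiotics, by a median of -1.30 on the log2 scale (25 adjusted over the list alone). The heme effect on E2f2, a cell cycle transcription factor, differed by -1.71 ± 0.17 SE and on Slpi by -2.23 ± 0.29. The NRF2 and PPAR lists did not pass the test of a difference. In all, 1266 genes had a more positive and 1004 a more negative heme effect with antibiotics, and 433 of the 2270 differed by at least 2-fold.

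The mitosis list had an adjusted p of 6.22e-32 for the difference, and adjusted p = 0.147 with an estimated correlation. Differences in single genes were -1.59 for Bub1, -1.53 for Cdk1, -1.30 for Birc5 and -1.01 ± 0.17 for Mki67 (adjusted p = 0.000918). DNA replication and S phase genes had a smaller effect in 20 of 25 cases (23 adjusted over the list alone, median -0.78, adjusted p = 2.08e-14, and adjusted p = 0.268 with an estimated correlation). Rrm2 differed by -1.46 and Tk1 by -1.07. The smooth muscle list differed by a median of 2.09, with 12 of 14 members higher and none lower (13 adjusted over the list alone, adjusted p = 2.59e-07, and adjusted p = 0.398 with an estimated correlation). Mitosis medians within lower and upper replicate numbers were -1.13 and -1.46.

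The heme effect on macrophage genes was smaller in 15 of 20 cases (15 adjusted over the list alone), with Adgre1 at -1.14 (adjusted p = 7.76e-10, and adjusted p = 0.268 with an estimated correlation). On cholesterol synthesis genes it was smaller in 11 of 19 cases (12 adjusted over the list alone), with Fdps at -0.97 (adjusted p = 8e-07, and adjusted p = 0.366 with an estimated correlation). On enteroendocrine genes it was more positive in 11 of 23 cases and more negative in 1 (13 and 1 adjusted over the list alone), with Cpe at 1.93 (adjusted p = 2.59e-07, and adjusted p = 0.0496 with an estimated correlation). On xenobiotic metabolism genes it was more positive in 8 of 16 cases (10 adjusted over the list alone), with Abcc2 at 2.08 and Ces2a at 1.54 (adjusted p = 8e-07, and adjusted p = 0.208 with an estimated correlation). On clock genes it was more positive in 8 of 16 cases and more negative in none (10 and 1 adjusted over the list alone), with Per3 at 1.79 (adjusted p = 0.000823, and adjusted p = 0.147 with an estimated correlation). Interferon-stimulated genes had a more negative effect in 7 of 22 cases (9 adjusted over the list alone, adjusted p = 1.14e-05, and adjusted p = 0.409 with an estimated correlation). With the smooth muscle score as a covariate that list had an adjusted p of 0.0748. The calls of 4 of these single genes ended there as well, Adgre1 at -0.84 (adjusted p = 0.0919), Fdps at -0.80 (0.129), Cpe at 0.79 (0.0711) and Per3 at 1.35 (0.0508). Abcc2 at 1.67 (0.022) and Ces2a at 1.73 (0.00185) stayed called. Without the 3 control arrays of highest muscle score the calls of Adgre1 (-0.74, 0.0993), Fdps (-0.69, 0.0943), Cpe (1.12, 0.193) and Abcc2 (1.61, 0.0681) ended. The muscle difference of 2.09 stood beside each of these lists.

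The NRF2 list had a median difference of 0.03 (adjusted p = 0.755), with 1 of 25 members more positive and 3 more negative, over all genes tested and adjusted over the list alone. Hmox1 differed by -0.34 ± 0.24 (adjusted p = 0.376), the peroxidase Gpx2 by -0.64, Abcc1 by 0.61, Slc7a11 by -1.27 and the transketolase Tkt by -0.32. The Slc7a11 call ended without control replicate 1 or 2, control plus antibiotics replicate 2 or 4, or heme replicate 3 or 4 (adjusted p 0.0534 to 0.069). That of Tkt ended without control replicate 1 or 2, control plus antibiotics replicate 1, 2 or 4, any heme array, or heme plus antibiotics replicate 3, 4, 5 or 6 (adjusted p 0.0507 to 0.0874). Both calls ended with array weights (0.0601 and 0.0594) and with the replicate number as a block (0.0575 and 0.0849). Slc7a11 stood at -1.33 (0.166), Tkt at -0.23 (0.396) and Abcc1 at 0.48 (0.096) with the smooth muscle score as a covariate, and none of them was called. Without the 3 control arrays of highest score, which leaves a lone control, they stood at -1.20, -0.31 and 0.59. None was called there either, though these sizes are close to those of the main fit.

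The PPAR list had a median difference of -0.05 (adjusted p = 0.596). Fabp1 alone was called, at -1.09, with 2 of 24 at an unadjusted p below 0.05 and 0 adjusted over the list alone. Its call ended without control replicate 1 or 2, control plus antibiotics replicate 3, or heme replicate 1 or 4 (adjusted p 0.0508 to 0.0614). It also ended with the replicate number as a block (-1.06, 0.0652), array weights (-0.88, 0.0836), the smooth muscle score as a covariate (-0.90, 0.27) and without the 3 control arrays of highest score (-1.05, 0.268). Fry gave the list an adjusted p of 0.857. These values do not show that the heme effects on both lists were equal.

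**Figure D2:**
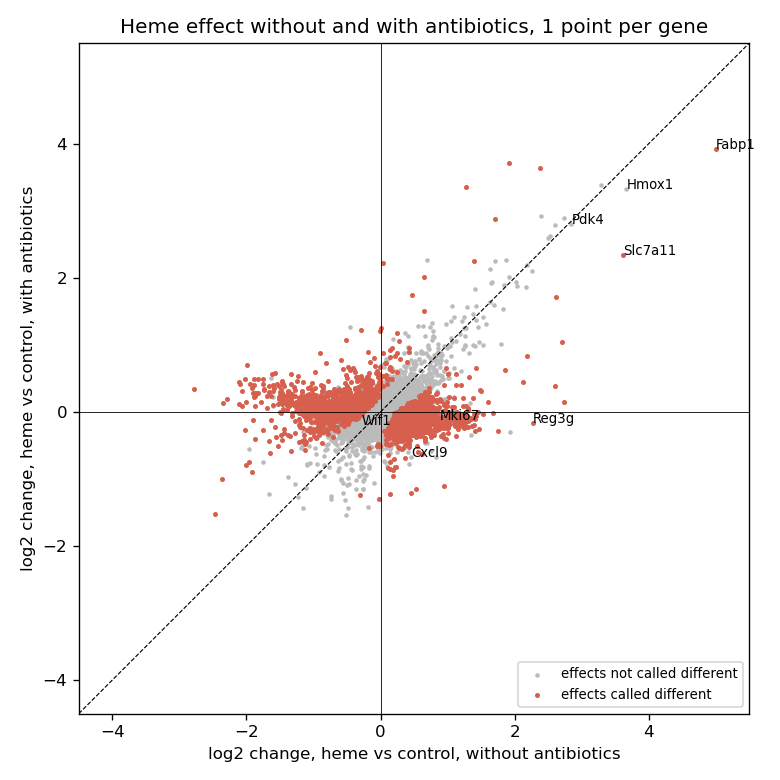
Log2 change from control to heme without antibiotics (x axis) against the log2 change with antibiotics (y axis), 1 point per tested gene, with the line of equal effects dashed. Genes whose effects were called different are coloured; Fabp1, Hmox1 and Pdk4 were above 2 on both axes, whereas Mki67 and Reg3g lay near 0 on the y axis, at -0.12 and -0.16.

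Over the 4453 genes called without antibiotics, the median heme change with antibiotics was 7.85% of that without, with a jackknife SE of 7.02%, and 13.5% with the filter at 100. For the 2171 that rose the value was 14.3%, and for the 2282 that fell it was 3.45%. These genes come from the comparison in which control scrapings had more muscle transcripts. The share was not computed with the smooth muscle score as a covariate or without the 3 control arrays of highest score. Choosing genes by their effect inflates the denominator, and choosing them in 2 arrays per group and measuring them in the other arrays gave 8.92% on average over 36 splits, with a range of 0.977% to 16.7%. Leaving out control plus antibiotics replicate 2 gave 4.36% and leaving out heme plus antibiotics replicate 3 gave 12.5%. Across all tested genes, which are not independent replicates, both heme effects correlated with r = 0.289. Called in both were 299 higher genes, against 77.7 for independent lists, and 118 lower genes, against 44.1, and 50 were called in both in opposite directions. Of 3986 genes called without but not with antibiotics, 1862 were called as different. With the smooth muscle score as a covariate 522 genes had different heme effects, and without the 3 control arrays of highest score 305. Within lower replicate numbers alone there were 1921 and within upper numbers alone 343.

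The fourth comparison asked what antibiotics change on the control diet. Interferon-stimulated genes rose in 20 of 22 cases, by a median of 1.03 on the log2 scale, and MHC class II genes in 8 of 9 cases, by 1.23. Mitosis genes rose in 25 of 25 cases, by 0.72. Oas3, an antiviral enzyme, went from a log2 value of 5.91 ± 0.38 to 8.02 ± 0.53 (n = 4 each), and the chemokine Ccl8 rose by 1.98 ± 0.25 from a level near the filter's minimum. Smooth muscle genes fell in 13 of 14 cases, by a median of 1.61. Antibiotics raised 795 genes and lowered 1105, and with each array centred on one median the split was 1043 higher and 803 lower (41.8% and 56.5% higher). The 1900 calls were 1171 with the filter at 100 and 866 with only both groups in the fit.

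The interferon list (22 higher adjusted over the list alone) had an adjusted p of 5.1e-22, and adjusted p = 0.119 with an estimated correlation. Usp18 rose by 2.00 and Oas2 by 1.82. The MHC class II list (8 adjusted over the list alone) had an adjusted p of 4.4e-11, and adjusted p = 0.119 with an estimated correlation, with H2-DMa at 1.60 and H2-Aa at 1.54. T and NK cell genes rose in 13 of 19 cases (16 adjusted over the list alone), with Cd4 at 1.1 and Cd5 at 0.91 (adjusted p = 3.45e-15, and adjusted p = 0.101 with an estimated correlation). Macrophage genes rose in 14 of 20 cases (15 adjusted over the list alone), with Lyz2 at 0.86 (adjusted p = 2.78e-12, and adjusted p = 0.17 with an estimated correlation). B and plasma cell genes rose in 9 of 17 cases (17 adjusted over the list alone), with Cd79b at 0.83 (adjusted p = 1.77e-11, and adjusted p = 0.131 with an estimated correlation). Beside these lists stood the smooth muscle fall of 1.61 (14 lower adjusted over the list alone, adjusted p = 1.01e-08, and adjusted p = 0.288 with an estimated correlation). Neuron and glia genes fell in 10 of 13 cases (12 adjusted over the list alone, adjusted p = 1.01e-08, and adjusted p = 0.191 with an estimated correlation), with Stmn2 at -1.68. Without the 3 control arrays of highest muscle score the muscle and neuron lists were no longer called. Those arrays were picked by their muscle score, with which the neuron score moved, so these lost calls are no separate evidence. Interferon medians within lower and upper replicate numbers were 1.1 and 0.87.

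The mitosis list (25 adjusted over the list alone) had an adjusted p of 9.28e-27, and adjusted p = 0.119 with an estimated correlation, with Bub1 at 0.92, Top2a at 0.91 and Mki67 at 0.58 ± 0.13. S phase genes rose in 16 of 25 cases (22 adjusted over the list alone, adjusted p = 1.8e-15, and adjusted p = 0.176 with an estimated correlation), with Tk1 at 0.71. Cholesterol synthesis genes rose in 12 of 19 cases (12 adjusted over the list alone, adjusted p = 1.59e-09, and adjusted p = 0.191 with an estimated correlation), with Cyp51 at 0.62. PPAR targets had a median of -0.06, with 0 of 24 called by limma, 0 adjusted over the list alone and 3 lower at an unadjusted p below 0.05 (fry adjusted p = 0.533), and Hmox1 stood at 0.09 ± 0.18. The smooth muscle fall of 1.61 stood beside these lists as well, and mitosis medians within lower and upper numbers were 0.62 and 0.83.

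With the smooth muscle score as a covariate 158 genes were called in place of 1900, and the calls of Lyz2, Cd79b, Stmn2, Cyp51 and Mki67 ended (adjusted p 0.0579 to 0.372). Their log2 changes were then 0.67 for Lyz2, 0.79 for Cd79b, 0.53 for Cyp51 and 0.66 for Mki67, and -0.50 for Stmn2 against -1.68 without the covariate. Of the 19 lists called by camera, 13 kept their call with the covariate. Of 73 called gene results followed, 17 were kept with it, 53 lost and 3 turned. Without the 3 control arrays of highest score 2 genes were called by limma (Chgb at -0.73 and Muc1 at -1.36, picked after their values were seen), and 1427 had an unadjusted p below 0.05. The count was 1076, 1099 or 1106 without control replicate 2, control replicate 1 or control plus antibiotics replicate 3, and 1761 and 44 within lower and upper numbers alone. The heme and antibiotic effects on the control diet share their control arrays. Their log2 changes correlated across genes with r = 0.684 and a covariance of 0.0764, against 0.499 and 0.00854 in 100 simulations with no effect. With the control arrays split between both effects r was 0.553 on average over 6 splits. Higher in both were 454 genes (117.9 for independent lists) and lower in both 919 (172.3). No effect simulated with the same control arrays gave 0 such calls, but 401 higher and 537 lower in both for lists of the real sizes. With the control arrays split, 195 were higher in both (43.9 for independent lists) and 242 lower (49.8) on average. Part of the overlap can come from the shared arrays, and a shared effect is not read from it.

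The last comparison asked what antibiotics change on the heme diet. Reg3b and Reg3g, antibacterial lectins, fell by 4.2 ± 0.70 and 3.18 ± 0.51 on the log2 scale (heme n = 4, heme plus antibiotics n = 6), the former 18.4-fold. Mitosis genes fell in 22 of 25 cases, by a median of 0.56. Slc5a4b rose by 2.02 ± 0.19 and Abcc2 by 1.98 ± 0.22, and 8 of 16 xenobiotic metabolism genes rose. In all 373 genes were higher and 443 lower with antibiotics, and 41 of the 816 differed at least 2-fold.

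The mitosis list (25 lower adjusted over the list alone) had an adjusted p of 6.02e-25, and adjusted p = 0.144 with an estimated correlation, with Aurka at -0.75 and Cenpa at -0.73. The list of genes that respond to bacteria had 7 of 22 members lower and 2 higher (10 and 2 adjusted over the list alone, adjusted p = 0.00175, and adjusted p = 0.367 with an estimated correlation), with Slpi at -1.49. Unfolded protein response genes fell in 5 of 18 cases (8 adjusted over the list alone), with Sdf2l1 at -0.49 (adjusted p = 0.000365, and adjusted p = 0.444 with an estimated correlation). PPAR targets were called lower by camera, with mean scores of 9.95 in heme and 9.79 in heme plus antibiotics. Camera with an estimated correlation called no list in this comparison. Without heme replicate 3 or 4, or heme plus antibiotics replicate 3 or 4, camera's adjusted p for PPAR targets was 0.0784 to 0.218. Capg fell by 1.47, Dhrs9 by 1.42 and Trim29 by 1.33. The smooth muscle list had a median of 0.40 here, with 0 of 14 called by limma and 0 at an unadjusted p below 0.05 (fry adjusted p = 0.456), and camera gave an adjusted p of 0.0306, and adjusted p = 0.622 with an estimated correlation. Without heme replicate 1 or heme plus antibiotics replicate 3, 4 or 5 camera's adjusted p was 0.0865 to 0.181. Mitosis medians within lower and upper replicate numbers were -0.45 and -0.65.

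Xenobiotic metabolism genes rose in 8 of 16 cases (9 adjusted over the list alone), with Ces2a at 0.75 and the sulfotransferase Sult1a1 at 0.66 (adjusted p = 5.14e-12, and adjusted p = 0.0648 with an estimated correlation). T and NK cell genes rose in 4 of 19 cases (12 adjusted over the list alone), with Cd3g at 0.82 (adjusted p = 1.07e-08, and adjusted p = 0.144 with an estimated correlation). Interferon-stimulated genes rose in 7 of 22 cases (11 higher and 1 lower adjusted over the list alone), with Rsad2 at 1.23 (adjusted p = 1.47e-07, and adjusted p = 0.444 with an estimated correlation). Their medians within lower and upper replicate numbers were 0.93 and 0.09. Enteroendocrine genes rose in 4 of 23 cases (5 higher and 1 lower adjusted over the list alone), namely the hormone genes Gcg (1.15) and Cck (0.72) with Nts (0.77) and Chga (adjusted p = 1.08e-05, and adjusted p = 0.0648 with an estimated correlation). The Nts call ended without heme replicate 1, 2 or 3 (adjusted p 0.0518, 0.0736 and 0.0516) and with the replicate number as a block (0.0876). Clock genes rose in 5 of 16 cases (9 higher and 2 lower adjusted over the list alone), with Per3 at 1.15 and Per2 at 0.70 (adjusted p = 0.000164, and adjusted p = 0.0709 with an estimated correlation). The digestive peptidase Enpep rose by 1.91 ± 0.16, the amino acid transporter Slc6a19 by 1.93 and the sucrase Sis by 1.69. The smooth muscle median of 0.40 stood beside these lists too.

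Without heme replicate 4, 1 or 2 the count of called genes was 461, 479 or 480 in place of 816. Within lower replicate numbers alone 355 genes were called and within upper numbers alone 19, the latter from 2 against 3 arrays.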

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

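The tests of the relation of neuron to muscle scores, of the Arntl arm of the clock, of the order of the arrays and of shuffled arrays, and the smooth muscle settings for lists and genes of the difference, were chosen after the result was seen, and the others before. A value per array stands here where it lay far from the rest of its group. Of 456 sets of values tested, 14 met that measure, where 22.8 are expected at 1 in 20 by chance.

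Among list scores (mean log2 expression), crypt base genes stood at 7.96 in control plus antibiotics replicate 1. Antimicrobial genes stood at 7.57 and oxidative phosphorylation genes at 10.96 in heme plus antibiotics replicate 3. The p53 target score was 7.70 in heme replicate 3, the tight junction score 9.27 in heme plus antibiotics replicate 2 and the adipocyte score 7.09 in heme replicate 1. Among single genes, Muc2 was at 13.33 in control replicate 3, Car1 at 13.34 in heme plus antibiotics replicate 6, Abcc4 at 7.15 in control replicate 1 and Cxcl9 at 7.37 in control plus antibiotics replicate 4. Reg3b was at 8.89 in heme replicate 1, Mcpt2 at 4.09 in control replicate 2 and 4.15 in control plus antibiotics replicate 3, and Lpcat4 at 8.19 in heme plus antibiotics replicate 4.

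The heme effect differed with antibiotics, by the test of the difference, for 2270 genes and 20 lists, of which 1, enteroendocrine genes, was called with an estimated correlation. Adding the smooth muscle covariate kept 12 of the lists, and of 91 gene differences followed 25 were kept, 63 lost and 3 turned, Cnn1 to -0.0094 and Des to -0.13 among them. The 8 lists lost there were interferon-stimulated genes (adjusted p = 0.0748), MHC class II (0.0689), oxidative phosphorylation (0.0631), antimicrobial genes (0.195), sulfide oxidation (0.195), T and NK cells (0.376), inflammatory cytokines (0.767) and smooth muscle itself (0.985). Without the 3 control arrays of highest muscle score 16 of the 20 lists and 19 of the 91 gene differences were kept, and 72 were lost. The lists lost were antimicrobial genes (0.223), ribosome biogenesis (0.223), inflammatory cytokines (0.574) and sulfide oxidation (0.0524). The heme effect was more positive with antibiotics for Pln (3.12), Pcp4 (2.55), Stmn2 (2.51), Calb2 (2.50), Epha7 (2.48), Nmu (2.48, with a heme mean of 3.97 below the filter's minimum of 20 linear, so not an exact size), Cnn1 (2.38), Hspb1 (2.37, with other transcript clusters down to -0.0083), Des (2.36) and Tacr2 (2.31). Each of these genes had its highest group mean in control, where muscle transcripts were also highest. Pln averaged 7.93 there, against 5.84 in control plus antibiotics, 5.15 in heme and 6.17 in heme plus antibiotics. Cnn1 and Des are on the smooth muscle list and Stmn2 is on the neuron and glia list. The heme effect was more negative with antibiotics for Clca4b (-2.60), Reg3g (-2.43), Slpi (-2.23), Fer1l4 (-2.04), Tnfrsf8 (-1.73), E2f2 (-1.71), Mfsd2a (-1.70), Apol7c (-1.69), Capg (-1.68), Usp18 (-1.67), Birc5 (-1.30) and Mki67 (-1.01). Lists with a positive median difference were smooth muscle (2.09), neurons and glia (1.35), clock (0.67), enteroendocrine (0.56), xenobiotic metabolism (0.46) and tuft cells (0.33). Negative medians were -1.30 for mitosis, -0.92 for MHC class II, -0.78 for S phase, -0.70 for macrophages, -0.58 for interferon-stimulated genes, -0.57 for cholesterol synthesis, -0.45 for B and plasma cells and -0.42 for antimicrobial genes. Smaller ones were -0.24 for the unfolded protein response, -0.24 for sulfide oxidation, -0.22 for inflammatory cytokines, -0.20 for oxidative phosphorylation, -0.19 for ribosome biogenesis and -0.18 for T and NK cells. The inflammatory list was not called without control replicate 2 or 3, control plus antibiotics replicate 1, 2 or 3, heme replicate 1, 3 or 4, or heme plus antibiotics replicate 3, 4 or 6 (adjusted p 0.0575 to 0.145). The sulfide list was not called without control replicate 1, 2 or 4, control plus antibiotics replicate 1 or 3, heme replicate 4 or heme plus antibiotics replicate 3 (0.0524 to 0.0676), and its median was 0.01 within upper replicate numbers. Ribosome biogenesis was not called without heme replicate 3 or 4 (0.0588 and 0.0676), T and NK cells without control plus antibiotics replicate 3 (0.0754) and antimicrobial genes without control replicate 3 (0.0589). Transcript clusters with no single gene symbol enter no comparison above, and 9858 of them passed the filter on dim genes and were tested. Of these limma called 488 for heme without antibiotics, 57 with antibiotics, 120 for the difference, 112 for antibiotics on the control diet and 25 on the heme diet.

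Mitosis genes were higher in heme and in control plus antibiotics than in control, by a mean of 1.16 (SE 0.13) and 0.72 (SE 0.13), while control scrapings had more muscle transcripts. Dilution of epithelial RNA in the control scrapings would raise epithelial genes at large, but 24 genes shared by epithelial cells changed by 0.023 (SE 0.033) and 0.010 (SE 0.033). With the smooth muscle score as a covariate the mitosis means were 1.22 (SE 0.18) and 0.78 (SE 0.18), which counts against muscle content as the whole cause. Neuron and muscle scores moved together within groups over 18 arrays (Pearson r = 0.892, permutation p = 2e-05, Spearman rho = 0.862, permutation p = 3e-05, r = 0.904 without 2 arrays), so muscle wall carried along, with Cnn1 at 11.48 and Des at 11.42 in control, may lie behind both. Whether heme or antibiotics changed cell division, the biological explanation in this design, stays open and untested beyond these arrays.

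Clock genes were lower in heme than in control, with the Per arm (9 genes) at a mean of -1.25 (SE 0.18). With the muscle covariate that mean was -0.91 (SE 0.22), which counts against muscle content as the whole cause. The Arntl arm (5 genes) changed by 0.64 (SE 0.19), as another phase of the clock when tissue was taken would need. With the covariate it was 0.41 (SE 0.25), so this phase difference is a candidate explanation that may rest in part on the muscle content. The hour of tissue collection was not used here, and a diet effect on the clock and a different hour per group both stay open.

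Arrays of lower and upper replicate numbers stood apart in every group, with 18 of 18 on their own side along the first component of the deviations from group means (26.0% of that variance). Of 100000 random orders a share of 0.00043 parted as well, in a test chosen after the parting was seen. Between lower and upper numbers 3461 genes differed, and 3750 with the muscle covariate, which counts against muscle content as the source. Upper numbers were higher for ribosome biogenesis (median 0.16, adjusted p = 0.00128), NRF2 targets (0.14, 0.00184), PPAR targets (0.11, 0.00714), S phase (0.14, 0.0222) and cholesterol synthesis (0.14, 0.0364), all with adjusted p = 0.99 with an estimated correlation. The labels give no batch, so a shared day or handling remains a possible explanation and no biological one was tested.

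Counts of called genes were set against other splits of the same arrays into groups of the same sizes. For heme with antibiotics and for antibiotics on the heme diet under 5% called as many. Among splits with lower and upper numbers as in the real one, only the real one did, 1 of 47 and 1 of 51. This argues against chance without excluding it, and needs arrays that can be exchanged within those numbers. On the 2 comparisons with control, of 4 against 4 arrays, the same holds only if arrays can be exchanged freely. There 18 of the 35 splits hold lower and upper numbers as in the real one, and 8 part every same-numbered pair, too few for a share under 5%. Heme without antibiotics called 4453 genes in 1 of 35 splits, the real one, and limma called 0 in every other split. The highest count at an unadjusted p below 0.05 was 3036 there, against 5897 in the real split. All 7 other splits that part every same-numbered pair were among those at 0. Heme with antibiotics called 807 against a highest other of 106 in 1 of 100 drawn splits. The difference called 2270, and 3 of 100 splits, the real one included, called as many. The others, at 3339 and 2710, kept all 4 heme arrays in place and mixed the antibiotic arrays. Splits of the diet labels can thus keep 1 heme effect and undo the other, so they decide nothing about the difference. With the average heme and antibiotic effects removed first and the arrays shuffled within lower and upper numbers, 1 of 100 shuffles, the real one, called as many. The difference itself stays in the shuffled values and widens their spread, and the test was chosen after the result was seen. It therefore argues against chance differences between arrays without excluding them. Every other shuffle called 0 by limma, with at most 1485 genes at an unadjusted p below 0.05 against 4280. Antibiotics on the control diet called 1900 against 389 (1 of 35) and on the heme diet 816 against 11 (1 of 100). Splits that follow lower and upper numbers called 0 genes by limma in heme against control and in antibiotics on the control diet. Such splits put both treatments in each group, which widens the spread within groups. With the group means in the fit, 3461 genes differed between lower and upper numbers. The count of 0 therefore does not show that the numbers cannot produce calls.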

How the results depend on the processing

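The smooth muscle covariate, the control group without its 3 arrays of highest score, the block of lower or upper numbers and the arrays of lower or upper numbers alone were tried after the data were seen, and all other settings were planned. For the 515 gene results followed, 16286 values under alternatives gave 14687 with the same direction and side of the threshold, 1454 no longer past it, 136 newly past it and 9 reversed. Called genes numbered 4453, 807, 2270, 1900 and 816 in the order of the comparisons above, and 1171 and 866 in the fourth with the filter at 100, which tests fewer genes, and with only the groups compared. With the smooth muscle covariate they were 1640 in the first, 522 in the third and 158 in the fourth. Without the 3 control arrays, which leaves a lone control assumed to vary like the other groups, they were 1013, 305 and 2. The block of lower or upper numbers gave 1234 in the second and 1266 in the fifth, and kept every gene called, but of the lists 17 of 19, 21 of 21, 19 of 20, 18 of 19 and 19 of 19. Lower numbers alone gave 308 in the second and 355 in the fifth, and upper numbers alone gave 1395, 371, 343, 44 and 19, with 2 or 3 arrays per group. Leaving out 1 array gave 3409 to 4503, 524 (without control plus antibiotics replicate 2, and 528 without replicate 3) to 858, 1579 to 2521, 1076 (without control replicate 2, 1099 without control replicate 1, 1106 without control plus antibiotics replicate 3) to 2097, and 461 (without heme replicate 4, 479 without replicate 1, 480 without replicate 2) to 883. Except where a setting uses fewer genes or arrays, the cause of these shifts was not tested. The share of the heme response kept with antibiotics, 7.85%, ran from 4.36% (without control plus antibiotics replicate 2) to 12.5% (without heme plus antibiotics replicate 3), was 13.5% with the filter at 100, and ran from 0.977% to 16.7% over 36 half-splits. That share was not computed under the smooth muscle settings.

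Lists called by camera were 19, 21, 20, 19 and 19, and with an estimated correlation 0, 2, 1, 0 and 0 (8, 14, 7, 9 and 6 at an unadjusted p below 0.05), where wider allowance for genes that move together is part of the test. Fry called 9 in the fifth, and the cause was not tested. Muscle genes reversed with the covariate, which by construction removes their own score: Des 0.15, Synm 0.14 and Cnn1 0.11 in the first, Cnn1 -0.0094, Des -0.13 and Synm -0.24 in the third, and Des 0.041, Cnn1 0.039 and Synm 0.13 in the fourth. Called gene results lost without some array numbered 9 of 109, 17 of 60, 25 of 91, 21 of 73 and 22 of 63. With the replicate number as a block, 4899, 571, 2265, 2135 and 607 genes were called, and 4307, 495, 1848, 1743 and 500 of the main calls were kept. It changed the calls of the fibroblast and iron lists in the first and no other list there, where 1 of 109 gene results was lost. In the other comparisons the correlations of same-numbered arrays lay between -0.23 and 0.31. In every comparison the labels give nothing that such arrays share beyond the number. Signal over background limits dim genes: without that filter 4418, 780, 2161, 1855 and 760 genes were called.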

Other observations

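The settings with the smooth muscle score or without 3 control arrays were chosen after the result was seen, and the list tests were not. Among groups not described so far, 7 of 18 unfolded protein response genes rose on heme without antibiotics (7 adjusted over the list alone, median 0.20, adjusted p = 0.0129, and adjusted p = 0.486 with an estimated correlation). Sdf2l1, a chaperone cofactor, rose by 0.71. The list had an adjusted p of 0.147 without the 3 control arrays of highest smooth muscle score. Of 18 crypt base and stem cell genes 6 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.13). The regulators Ascl2 and Rnf43 fell by 0.57 and 0.55 (list adjusted p = 0.0289, and adjusted p = 0.225 with an estimated correlation). Without control replicate 4 or heme replicate 3 that adjusted p was 0.082 or 0.0545. Mature surface colonocyte genes split, with 9 of 26 higher and 9 lower (10 and 10 adjusted over the list alone, camera adjusted p = 0.944, median -0.05 against a mean of 0.20). Clca4b rose by 2.74 and the phosphatase Alpi by 1.85, while the proton pump subunit Atp12a fell by 0.99. Goblet cell genes had 4 of 18 lower and 1 higher (4 and 1 adjusted over the list alone), with Clca1 at -0.45, and the list was not called (adjusted p = 0.0706). The smooth muscle median of -1.71 stood beside each of these lists.

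Proteases of mucosal mast cells rose on heme without antibiotics, Mcpt2 by 2.18 and Mcpt1 by 1.30, in a list of 8 that had 4 higher and 1 lower (4 and 1 adjusted over the list alone) and was not called (adjusted p = 0.262). Their heme effect differed with antibiotics by -1.35 and -1.24, calls that ended with the smooth muscle score as a covariate (-1.07 and -1.38, adjusted p = 0.206 and 0.104) and without the 3 control arrays of highest score (-1.14 and -1.41, adjusted p = 0.228 and 0.149). Of 7 growth factor ligands of the epidermal type 3 rose (3 higher and 1 lower adjusted over the list alone), and the list was not called (adjusted p = 0.274). Ereg rose by 1.34 and Nrg1 by 1.13, and the Ereg call ended with the smooth muscle score as a covariate (0.79, adjusted p = 0.29) and without the 3 control arrays of highest score (1.46, 0.174). In the list of injury and regenerative epithelium 6 of 15 rose and 3 fell (7 and 3 adjusted over the list alone, adjusted p = 0.181). The urokinase receptor Plaur rose by 1.47 and the coagulation factor F3 fell by 0.82. Hypoxia and glycolysis genes rose in 4 of 18 cases on heme with antibiotics (7 adjusted over the list alone), led by Ndrg1 at 0.87 and Bnip3 at 0.68 (adjusted p = 0.00229, and adjusted p = 0.134 with an estimated correlation).

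Camera called 7 of the 39 lists in none of the 5 comparisons. Their lowest adjusted p was 0.0569 for neutrophils, 0.0667 for endothelium, 0.0971 for p53 targets, 0.0971 for bile acid and short-chain fatty acid handling, 0.132 for injury and regenerative epithelium, 0.189 for mature surface colonocytes and 0.274 for growth factor ligands.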
